A study of Mus musculus with 16 samples.

How the data were processed

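Germinal centre B cells were isolated from immunised mice with a B cell isolation kit and sorted as B220+, PNA+ and CD95+ cells, and libraries were made from total RNA with the TruSeq RNA v2 kit, per the labels' protocols. The growth protocol gives 12 days after immunisation and a sample tag gives 10 days, and which is right was not settled. The deposited table held whole-number read counts per gene symbol for 48593 genes and 16 libraries, and no other sample column. The submitters' processing notes name CASAVA 1.8, HISAT2, featureCounts and the mm10 build, and versions of HISAT2 and featureCounts are not given in the sources used here. The strand setting is not given either, and the kit does not mark strand, so reads of overlapping or antisense genes cannot be told apart. Genes that share reads with near-identical copies, such as H2 paralogs, immunoglobulin segments and mitochondrially encoded genes with nuclear copies, are uncertain. Positions were taken from GENCODE M21 on GRCm38, the same assembly as mm10, which held 48069 of the 48593 symbols.

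Groups were read from the sample titles. The genotype stood in a tag of another name and several tags were shifted against their values, so the titles were used. The replicate numbers were given in accession order and only name a library. The labels do not say that each library came from a different mouse, so p values measure the spread between these libraries. The Cre driver of the knockout is not named in the labels. Counts of replicate pairs differed far beyond sampling noise, with chi-square per degree of freedom from 17.7 to 225, so no library was counted as a repeat of another. Xist counts above 1000, taken as female, occurred in 2 of 3 KO cohort WT, 1 of 3 KO, 1 of 3 RH cohort WT, 1 of 4 RH HET and 2 of 3 RH HOMO libraries.

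Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 16606, and libraries were scaled by TMM. A model with 5 group means was fitted to all 16 libraries, leaving 11 residual degrees of freedom, with the quasi-likelihood test (glmQLFit and glmQLFTest) and Benjamini-Hochberg adjustment over all tested genes. A gene was called at an adjusted p under 0.05. All adjusted p values of single genes come from this test unless another tool is named. The standard error of a log2 fold change is the fold change divided by the square root of its F statistic. The contrasts were KO minus KO cohort WT, RH HET minus RH cohort WT, RH HOMO minus RH cohort WT, RH HOMO minus RH HET, the RH HOMO effect minus the KO effect, and RH cohort WT minus KO cohort WT. CPM values use TMM-scaled library sizes.

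Before the data were examined, 36 gene lists with 807 entries were written, 803 of which were in the table. Lists with at least 5 measured genes were tested on log2 CPM (prior count 2) with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. No list was called with an estimated correlation in any comparison. Genes to be named were fixed by a rule before the data were examined. For KO, RH HET and RH HOMO against wild type the rule took the 6 largest rises and the 6 largest falls among called genes with a mean log2 CPM of at least 2 and no overlap between replicates, leaving out immunoglobulin and T cell receptor segments, predicted gene models and pseudogenes. It added the 2 called members of each list with the smallest p, or 1 member if none was called, all MHC class II members, Crebbp and Ep300. For RH HOMO minus RH HET and for the difference of effects it took the 3 largest in each direction, and the overlap of replicates was not used for the difference of effects.

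The alternatives, fixed before the data were examined unless stated, were DESeq2 size factors, no immunoglobulin or T cell receptor genes, no count filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with quality weights, an adjusted p of 0.1, an absolute log2 fold change of at least 1, only the libraries compared, the conflicting library in the KO cohort, all 6 wild type libraries as 1 control group, and leaving out each library. A term for sex, a term for the mitochondrial share, leaving out RH cohort WT 1 and RH HOMO 2 together, and leaving out mitochondrial and rRNA-like genes were added after seeing the data.

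The test was run on simulated counts drawn from the real means, dispersions and library sizes, with 200 changed genes. For KO it recovered 82% of genes changed by a log2 fold of 1 and 94% of those changed by 2, among 16278 genes. For RH HET it recovered 81% and 99% among 16275 genes, and for RH HOMO 87% and 98% among 16258 genes. Of the simulated calls, 5.13%, 4.66% and 3.54% were false. Camera found the shifted list each time and also called 0, 3 and 0 unshifted lists. Each gene was drawn on its own, so the simulated counts lack the correlation between genes of the real libraries. The shares of false calls and the camera results may therefore look better than in the data. Splits of the libraries into other groups of the same sizes were all fitted where 35 or fewer exist, and otherwise 100 were drawn. At first 40 had been drawn, and the number was raised after their results were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.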

Results

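Germinal centres are the sites in lymphoid tissue where B cells mutate their immunoglobulin genes and are selected for antigen binding, and Crebbp encodes a histone acetyltransferase that is often mutated in lymphomas arising from these cells. RNA was sequenced from germinal centre B cells (B220+, PNA+, CD95+) sorted from mice immunised with sheep red blood cells. The labels give 5 groups in 2 cohorts. The knockout cohort held 3 wild type libraries (KO cohort WT) and 3 libraries from mice with a knockout of Crebbp in germinal centre B cells (KO). The knock-in cohort, in which an arginine-to-histidine allele of Crebbp was studied, held 3 wild type libraries (RH cohort WT), 4 heterozygous libraries (RH HET) and 3 homozygous libraries (RH HOMO). The deposited values were read counts per gene, and totals per library ran from 41362856 in RH HET 4 to 93040297 in KO cohort WT 2. Of 48593 genes in the table, 16606 passed the count filter and were tested. Spearman correlations between libraries of 1 group lay between 0.977 and 0.991. RH cohort WT 1 and RH HOMO 2 stood apart on the first principal component, at 49.1 and 43.3, with the other 14 libraries between -31.0 and 14.2.

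The first question was what the loss of Crebbp changed in germinal centre B cells. Crebbp itself (chromosome 16, 4081328 to 4213997 on the minus strand, GRCm38) was counted at 131, 127 and 149 CPM, counts scaled to the library total, in the KO cohort WT libraries and at 123, 137 and 108 CPM in the KO libraries. The group means were 135.5 ± 11.6 and 122.6 ± 14.5 CPM (SD, n = 3 each), and the log2 difference of -0.15 ± 0.17 (SE) did not pass the test (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.826). The counts cover the whole gene and the labels do not give the deleted part, so this mRNA level checks neither the labels nor the loss of the protein. Ep300, which encodes the closest paralog of Crebbp, differed by 0.02 ± 0.23 (adjusted p = 0.986).

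KO cells had less mRNA for the genes that present peptides on MHC class II. All 14 measured members of that list had negative log2 differences, with a median of -0.41, and 6 members fell past the threshold while 0 rose. The alpha chain gene H2-Aa fell from 1597 ± 85.9 to 1045 ± 85.0 CPM (SD, n = 3 each), a log2 change of -0.61 ± 0.11 (SE, adjusted p = 0.0108). The other calls were H2-Eb1 (-0.50), H2-DMa (-0.47) and H2-DMb2 (-0.47), which encode a beta chain and peptide loading factors, H2-Oa (-0.58), which encodes a modulator of loading, and Lgmn (-0.56), which encodes a lysosomal protease. Ciita, the transcriptional activator of class II genes, was at -0.16 ± 0.13 and Cd74, the invariant chain, at -0.34 ± 0.14, and neither passed the test. Adjusted over the list alone, 10 members were lower. The camera set test gave an adjusted p of 9.59e-12 and fry gave 0.00319, but camera gave adjusted p = 0.176 with an estimated correlation. The markers of dendritic cells, which also carry class II molecules, had 6 of 7 measured members negative in KO, with a median of -0.51. Flt3 was the 1 member called, camera gave adjusted p = 0.0936 and adjusted p = 0.403 with an estimated correlation, and fry gave adjusted p = 0.0347.

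**Figure D1:**
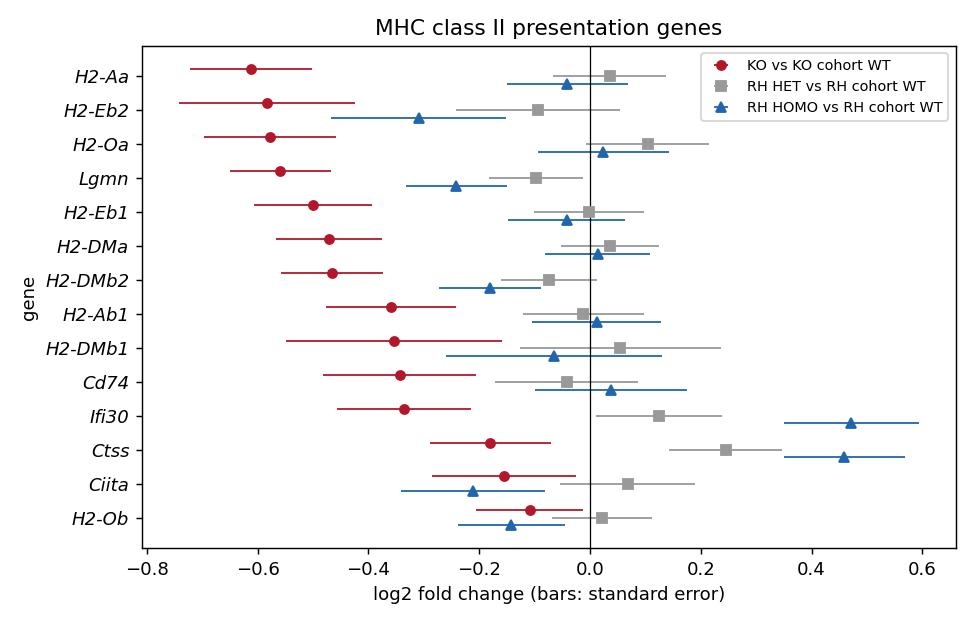
Log2 fold changes (x axis) of the 14 measured MHC class II presentation genes (y axis) in KO, RH HET and RH HOMO, each against the wild type libraries of its own cohort, with bars for the standard error. All 14 KO points lie left of 0, with H2-Aa lowest at -0.61, whereas the RH HOMO points lie on both sides.

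Over all tested genes, KO libraries had 95 genes higher and 121 genes lower than KO cohort WT. The named genes with the largest rises were Adgrl2, an adhesion receptor (log2 change 1.99 ± 0.27 SE), Ppm1e, a protein phosphatase (1.64 ± 0.24), Inppl1, an inositol phosphatase (1.59 ± 0.15), Gfi1, a transcriptional repressor (1.5 ± 0.26), Dmpk, a protein kinase (1.47 ± 0.20), and Kdm5b, a histone demethylase (1.33 ± 0.24). Within the naming rule, the largest falls were in Sh2d1b1, an adaptor of SLAM family receptors (-2.65 ± 0.28), Sh2d2a, another signalling adaptor (-1.61 ± 0.20), Pde2a, a cyclic nucleotide phosphodiesterase (-1.58 ± 0.23), Rgs13, a regulator of G protein signalling in germinal centre B cells (-1.58 ± 0.23), Csf2rb, a shared cytokine receptor chain (-1.55 ± 0.26), and Ifnlr1, a chain of the interferon lambda receptor (-1.51 ± 0.25). Adjusted p values of these 12 genes ran from 5.12e-05 for Inppl1 to 0.0108 for Kdm5b. Rgs13 fell from 241.8 ± 26.7 to 81.0 ± 15.8 CPM, and Inppl1 rose from 25.4 ± 1.45 to 76.6 ± 12.4 CPM (SD, n = 3 each).

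Named members of other lists were also called. The inhibitory Fc receptor gene Fcgr2b (0.35) and the transcription factor gene Lmo2 (0.45) rose, as did the p53 targets Zmat3 (0.66) and Tnfrsf10b (1.37), 2 of 21 measured members of their list. The glycolytic enzyme gene Pfkp (-0.49) and the oxidase gene Ero1lb of protein folding (-0.43) fell. Of marker lists for other cells, Flt3 of the dendritic cell list fell (-0.51) and Car2 of the erythroid list rose (1.0). Of the mitochondrially encoded genes, mt-Co2 was higher by 2.97, from 0.721 ± 0.28 to 5.70 ± 6.46 CPM, with 13 CPM in KO 1, and mt-Co2 was at 1.49 without that library (adjusted p = 0.369). Camera placed 6 of 34 tested lists lower and 0 higher, namely MHC class II and MHC class I presentation, light zone genes, B cell receptor signalling, cytosolic ribosomal proteins and markers of NK cells and stroma. The only called member of the light zone list, Lmo2, and of B cell receptor signalling, Fcgr2b, rose against the direction of its list. MHC class I presentation had 18 of 21 measured members negative, a median of -0.15 and 0 members called (adjusted p = 0.00159, and adjusted p = 0.726 with an estimated correlation). None of the 6 passed with an estimated correlation.

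The KO comparison was fitted together with all 16 libraries. Leaving out any 1 of its 6 libraries left 18 to 40 genes higher and 18 to 47 lower, with H2-Aa at -0.56 to -0.67 but no longer called without KO 1, KO 3, KO cohort WT 2 or KO cohort WT 3, and fitting the 6 libraries alone gave 331 higher and 368 lower.

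The second question was what the RH allele changed when heterozygous. RH HET libraries differed from RH cohort WT in 3 genes, which all lie on the distal part of chromosome 6. Plbd1, a phospholipase gene (136612070 to 136661928), rose by 1.59 ± 0.23 (SE), from 4.93 ± 2.18 CPM (SD, n = 3) to 14.9 ± 0.528 CPM (SD, n = 4), with adjusted p = 0.0263 by edgeR. Apobec1, an RNA editing deaminase gene (122577792 to 122602444), rose by 0.55 ± 0.08 (adjusted p = 0.0263). Dusp16, a phosphatase gene of MAP kinase signalling (134715468 to 134792625), had a log2 change of -0.73 ± 0.12 (adjusted p = 0.0481). Crebbp was at 0.36 ± 0.16 (adjusted p = 0.668), and Fcgr2b was at 0.43 ± 0.07 (adjusted p = 0.0578).

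By camera at the preset correlation alone, some gene lists were shifted by small amounts in RH HET. Camera placed 5 lists higher, among them the interferon gamma response (median 0.26, adjusted p = 0.00019) and MHC class I presentation (median 0.12, adjusted p = 0.018), and 9 lower, among them MYC targets and ribosome biogenesis, with all 35 measured members negative (median -0.23, adjusted p = 3.08e-09), and DNA replication (median -0.15, adjusted p = 6.08e-07). With an estimated correlation these 4 lists had adjusted p = 0.576, adjusted p = 0.705, adjusted p = 0.651 and adjusted p = 0.651, and fry called 0 lists, with adjusted p = 0.369 for MYC targets. A term for the mitochondrial share turned the median of MYC targets to 0.01. Follicular naive B cell markers were among the 5 higher lists (15 of 18 positive, median 0.19, adjusted p = 0.0048, and adjusted p = 0.705 with an estimated correlation). Macrophage and monocyte markers had 11 of 18 members positive and a median of 0.57, but camera did not call that list (adjusted p = 0.329). The MHC class II list had a median of 0.03 with 0 of 14 members called. The mitochondrially encoded genes were lower as a list (median -0.56, camera adjusted p = 6.08e-07, adjusted p = 0.465 with an estimated correlation), and mitochondrial shares of all counts were 7.34%, 7.15% and 4.72% in RH cohort WT against 3.93% to 5.84% in RH HET. The term for that share left 0 genes and 1 list higher and 0 genes and 3 lists lower. Leaving out RH cohort WT 2 or any of the 4 RH HET libraries, or fitting the 7 libraries alone, called 0 genes by edgeR, with 1054 at an unadjusted p under 0.05 in the fit of 7, whereas DESeq2 on all libraries called 17 higher and 34 lower and limma-voom 127 and 117.

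In RH HOMO, most genes of MHC class I presentation and of the interferon gamma response had positive differences from RH cohort WT. Few of them passed the test singly. Of 22 measured interferon gamma response genes, 20 had positive differences (median 0.44), 4 rose past the threshold and 0 fell. They included the transcription factor gene Irf1, which rose by 1.10 ± 0.21 (SE) from 42.1 ± 3.83 to 90.0 ± 17.4 CPM (SD, n = 3 each, adjusted p = 0.0125), and the GTPase gene Irgm1, which rose by 1.05 ± 0.22 (adjusted p = 0.0207). Of 21 measured MHC class I genes, 20 had positive differences (median 0.30) and 2 rose, B2m, the light chain of class I molecules (0.61 ± 0.14, from 579.7 ± 52.6 to 885.9 ± 115 CPM, adjusted p = 0.0275), and Tapbpl, a peptide editor (0.47 ± 0.10, adjusted p = 0.0259). Adjusted over the list alone, 11 interferon gamma response genes and 14 MHC class I genes were higher. Both lists had an adjusted p of 3.1e-08 by camera and 0.0326 by fry, and both had adjusted p = 0.395 with an estimated correlation. The RH HET libraries differed among themselves in some of these genes. Irf1 was at 47.9 and 41.4 CPM in RH HET 1 and 2 and at 79.3 and 72.7 CPM in RH HET 3 and 4. B2m was at 551 and 513 CPM in RH HET 1 and 2 and at 664 and 783 CPM in RH HET 3 and 4. Tapbpl, at 36.1, 30.5, 41.5 and 35.2 CPM in RH HET 1 to 4, did not divide them this way. Tapbpl lies on distal chromosome 6 (125223933 to 125231860), where a linked segment stays open, as set out under the other observations. MHC class II genes had a median of -0.04, with 1 of 14 higher, the protease gene Ctss (0.46 ± 0.11), and 0 lower. H2-Aa was at -0.04 ± 0.11.

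Across all genes, 96 were higher and 165 lower in RH HOMO. The named genes with the largest rises were Plbd1 (2.08 ± 0.24 SE), the glutathione transferase gene Gstt1 (1.53 ± 0.35), the inflammasome sensor gene Naip5 (1.41 ± 0.28), Gfi1 (1.36 ± 0.26), the calcium-binding protein gene Rcn1 (1.36 ± 0.20) and the steroid dehydrogenase gene Hsd17b11 (1.32 ± 0.21). Among genes that the naming rule allowed, the largest falls were in mt-Nd4l (-5.31), Eepd1 (-2.10 ± 0.22), Sh2d1b1 (-1.92 ± 0.27), Ifnlr1 (-1.82 ± 0.26), the phosphatase gene Dusp3 (-1.81 ± 0.27) and Shisa8 (-1.70 ± 0.26). The mt-Nd4l call rested on RH cohort WT 1, with 112 CPM against 2.13 and 1.94 CPM in the other wild type libraries, and was lost without it, with mt-Nd4l at -1.07 (adjusted p = 0.324).

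Named members of other lists were called in RH HOMO too. Fcgr2b rose by 0.79 ± 0.08, from 164.2 ± 3.85 to 284.3 ± 27.2 CPM (SD, n = 3 each, adjusted p = 0.000151), and Lmo2 rose by 0.39. Gpr183, a receptor that guides B cells out of follicle centres, rose by 0.92, and Cmpk2 of the type I interferon list by 0.99. Mef2b, a transcription factor gene of germinal centre B cells, was at -0.57, Smarca4, which encodes a chromatin remodelling ATPase, at -0.51, Arid3a at -0.59, Tle3 at -0.77 and Traf1 at -0.48, all past the threshold. Asns (-0.83) and Pfkp (-0.49) fell, as did the immunoglobulin constant genes Ighg1 (-0.57) and Iglc2 (-0.90). Thy1, a T cell marker, was higher by 2.16, from 0.300 ± 0.111 to 1.32 ± 0.47 CPM, and was the 1 call among 13 measured T cell markers. Camera placed 5 lists higher, adding the type I interferon response, apoptosis regulators and follicular naive B cell markers (median 0.20, adjusted p = 0.0442, and adjusted p = 0.828 with an estimated correlation). The type I interferon response had adjusted p = 0.828 and apoptosis regulators adjusted p = 0.433 with an estimated correlation. Camera placed 4 lower, namely dark zone genes (median -0.15, adjusted p = 0.000684, and adjusted p = 0.395 with an estimated correlation), germinal centre identity, DNA replication and mitochondrially encoded genes (median -0.62). The last 3 had adjusted p = 0.693, adjusted p = 0.828 and adjusted p = 0.512 with an estimated correlation, and a term for the mitochondrial share turned the median of DNA replication from -0.06 to 0.05. Mitochondrial shares were 4.32% to 5.28% in RH HOMO against 4.72% to 7.34% in RH cohort WT.

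Fitted on the 6 RH HOMO and RH cohort WT libraries alone, edgeR called 0 genes, with 1236 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0652, whereas DESeq2 on all libraries called 257 higher and 409 lower and limma-voom 535 and 585. Leaving out 1 library gave 34 genes higher without RH cohort WT 2, 38 without RH cohort WT 1 and 52 without RH HOMO 1, and 81 lower without RH cohort WT 2 and 106 without RH HOMO 1.

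**Figure D2:**
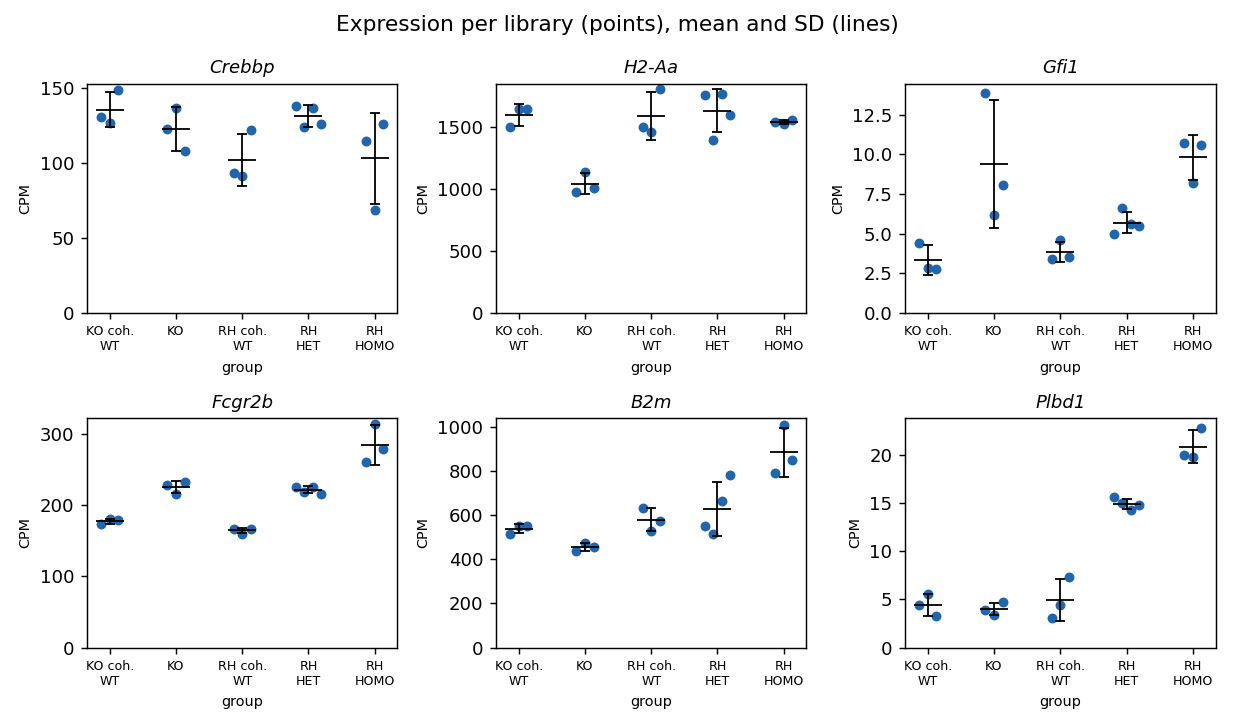
CPM (y axis, linear from 0) of 6 genes in each of the 16 libraries by group (x axis), with lines for the mean and SD. Crebbp overlaps between groups, H2-Aa is lower in the 3 KO libraries, Gfi1 is higher in KO and RH HOMO, Fcgr2b is higher in KO, RH HET and RH HOMO than in the wild types, and B2m and Plbd1 are highest in RH HOMO.

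Homozygous and heterozygous RH libraries were compared directly. By edgeR, 0 genes differed at an adjusted p under 0.05, 1889 had an unadjusted p under 0.05, DESeq2 called 36 higher and 96 lower, and limma-voom called 44 and 45. Camera placed 6 lists higher in RH HOMO, among them nuclear-encoded oxidative phosphorylation genes (34 of 35 positive, median 0.23, adjusted p = 2.31e-05) and MHC class I genes (19 of 21 positive, median 0.23, adjusted p = 3.68e-05). It placed 2 lower, germinal centre identity (17 of 23 negative, median -0.11, adjusted p = 0.0137) and chromatin regulators mutated in lymphoma (17 of 26 negative, median -0.18, adjusted p = 0.00917). These 4 lists had adjusted p = 0.91 with an estimated correlation, and the median of chromatin regulators turned to 0.002 without RH HOMO 2. Cytosolic ribosomal proteins had a median of 0.21 that turned to -0.06 without RH HOMO 2, where ribosomal protein genes took 8.84% of counts. Crebbp was at -0.35 ± 0.16 (adjusted p = 0.432).

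Whether the homozygous RH allele and the knockout changed the same genes was asked through the overlap of their calls, which use different control libraries. Of the 95 genes higher in KO and the 96 higher in RH HOMO, 16 were shared, where independent lists would share 0.549. Of the 121 and 165 lower genes, 24 were shared, where independent lists would share 1.20. Both sets of calls came from 1 fit of all 16 libraries, with a common estimate of the spread of each gene. The numbers for independent lists may therefore be too low a baseline. Fitted on only the libraries compared, RH HOMO had 0 calls, which leaves no gene to share. The shared rises included Gfi1, Adgrl2, Fcgr2b, Lmo2 and Hsd17b11, and the shared falls Sh2d1b1, Sh2d2a, Ifnlr1, Pde2a, Eepd1 and Pfkp. Fcgr2b (170958617 to 170976547) and Sh2d1b1 (170277320 to 170286769) lie near each other on chromosome 1. Whether a linked segment there joins these calls was not tested. Only 3 genes were called in opposite directions, Zfpm1, Crybg1 and the immunoglobulin segment Iglj2, which are named because they are few. Over all 16606 genes, which are not independent replicates, the fold changes had a Pearson correlation of 0.124. The overlap was 114 genes with DESeq2 and 8 to 62 when 1 library was left out, with 8 without KO cohort WT 2, 12 without KO 1, 16 without KO cohort WT 1 and 62 without RH HOMO 2.

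**Figure D3:**
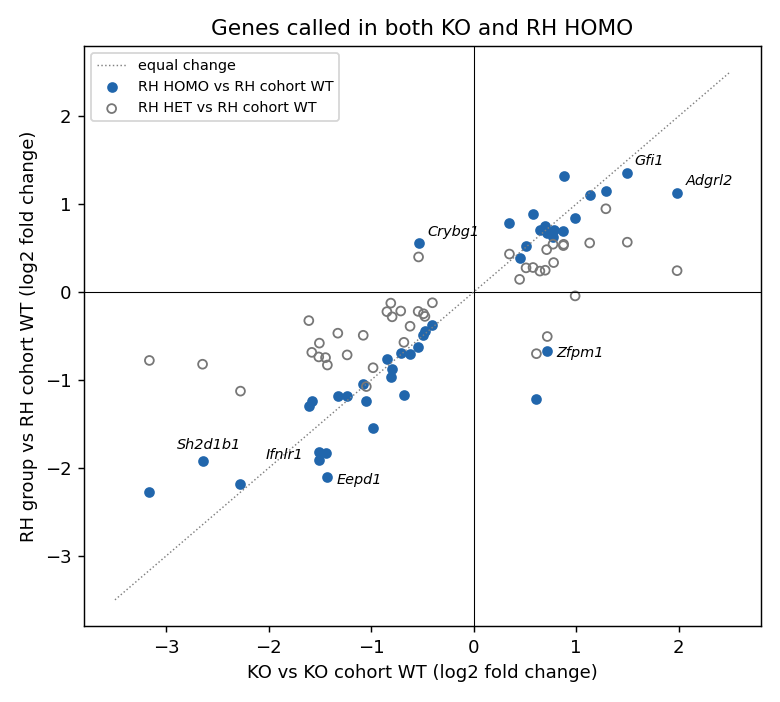
Log2 fold changes of the 43 genes called in both KO and RH HOMO, with the KO change on the x axis and the RH HOMO change (filled) or RH HET change (open) against RH cohort WT on the y axis and a dotted line of equal change. In 40 of them the KO and RH HOMO changes have the same sign, and Zfpm1 and Crybg1 are among the 3 that do not.

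The 3 genes called in RH HET were also called in RH HOMO in the same direction. These comparisons share the RH cohort WT libraries. Leaving out 1 library gave 0 to 7 shared genes, with 0 without any RH HET library. In 30 simulations of unchanged groups against those controls, 0 genes were shared and the mean correlation of fold changes was 0.551, where the observed one was 0.564. Each gene was drawn on its own there, so changes common to many genes of a library were absent and 0 shared genes may be too low. The covariance was 0.169 against a simulated mean of 0.123, a difference of 0.0463. With 3 control libraries, no split leaves 2 on each side, so part of the overlap may come from the shared controls.

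The difference between the RH HOMO effect and the KO effect was tested directly. Camera and fry called the MHC class I and class II lists for this difference, and the test with an estimated correlation called neither. All 21 MHC class I genes had positive differences of effect (median 0.44, camera adjusted p = 1.77e-12, fry adjusted p = 0.0207, and adjusted p = 0.20 with an estimated correlation), as did 12 of 14 MHC class II genes (median 0.38, camera adjusted p = 3.29e-07, fry adjusted p = 0.0207, and adjusted p = 0.246 with an estimated correlation). No single member of either list passed over all genes, whereas 12 class I and 7 class II genes did when adjusted over the list alone. The class II medians were -0.41 in KO and -0.04 in RH HOMO. Across all genes, 13 had a higher and 27 a lower RH HOMO effect. The largest named differences were in Il9r, a cytokine receptor gene (2.33 ± 0.43 SE), Plbd1 (2.22 ± 0.34) and Fxyd5 (1.81 ± 0.28), and in Dmpk (-1.86 ± 0.28), Dab2ip (-1.84 ± 0.25) and Lrrc32 (-1.75 ± 0.29). Immunoglobulin constant genes had a median of -0.44 (camera adjusted p = 0.0074, fry adjusted p = 0.0187, and adjusted p = 0.20 with an estimated correlation). Leaving out 1 library gave from 1 higher and 5 lower genes without KO cohort WT 2 to 22 higher and 45 lower without RH HOMO 2.

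The wild type libraries of the cohorts were compared to see how far the cohorts differed without a Crebbp allele. RH cohort WT had 527 genes higher and 313 lower than KO cohort WT, more than either allele changed within its cohort. The cohort and the wild type group cannot be told apart here, so no comparison between KO and RH groups was made without each cohort's own controls. One library titled as an RH wild type, RH cohort WT 1, carried a batch tag of the knockout cohort. Counting it there left 1 gene higher and 0 lower by edgeR, and leaving out 1 library gave from 1 higher and 2 lower genes without KO cohort WT 2 to 1119 higher and 749 lower without RH cohort WT 3.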

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

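The tests of technical explanations below were chosen after the results were seen, except the tests on RH cohort WT 1 in the wild type comparison and the splits for the shared calls. Counts among splits that keep the KO group together were also added after the results were seen. For the shared calls of KO and RH HOMO they replaced the planned reading of the 100 splits. The number of drawn splits was raised from 40 to 100 after the first draw had been seen.

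Effects of the RH HOMO genotype and of the knockout differed by the test of the difference itself in 13 genes in the positive and 27 in the negative direction. The named genes were Il9r (2.33), Plbd1 (2.22), Fxyd5 (1.81), Dmpk (-1.86), Dab2ip (-1.84) and Lrrc32 (-1.75). Of these, Plbd1 lies on distal chromosome 6, where a linked segment stays open. Lists with a difference by camera were MHC class I (median 0.44), interferon gamma response (0.40), MHC class II (0.38), cytosolic ribosomal proteins (0.24, but -0.04 without RH HOMO 2), CD40 and NF-kB targets (0.21) and light zone (0.17), and in the other direction mitochondrially encoded genes (-0.53), immunoglobulin constant regions (-0.44) and dark zone (-0.17). None of the 9 passed with an estimated correlation, where adjusted p was 0.20 at the lowest and 0.89 at the highest. Of 100 splits drawn from 200, in which labels were exchanged within each cohort, 4 called as many genes, with 40 for the real split and 543 for the highest other, a share below 0.05 that the first 40 splits, with 2 as large, did not reach. Whether the share fell below 0.05 therefore hung on the number drawn, and the split with 543 was counted as large in both draws. The share also says little because 90 of the 100 splits broke up the KO group. Other splits that reached 40 called 543, 116 and 41 genes. Those with 543 and 116 kept the KO group together, as 10 of the 100 did, and such splits are too few for a share under 0.05. The split with 543 reversed the KO labels only, so it adds the effects of the alleles in place of subtracting them. As many lists were called in 42 of the 100 splits, with 9 for the real split and 17 for the highest other.

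In 5 of 51 examined genes and in 1 of 7 library measures, 1 of the 4 RH HET libraries lay far from the other 3, where chance flags about 1 in 20. For RH HET 2 the gap as a share of the range was 0.90 for the ribosomal share of counts, 0.904 for Arid3a, 0.903 for mt-Nd4l, 0.867 for Ctss and 0.86 for H2-Eb2, and for RH HET 1 it was 0.843 for Lgmn.

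The fall of MHC class II genes in KO was 1 of the patterns weighed, and it did not rest on 1 library, since the list median of -0.41 ran from -0.49 to -0.36 when each of the 6 libraries was left out. Less RNA from follicular naive B cells would lower their markers at least as much, but these had a median of 0.10 and a lower quartile of -0.20, above the upper quartile of -0.34 of the class II list. A linked segment of chromosome 17, where the 9 H2 genes of the list lie, stays open, because the 5 members on other chromosomes had a median of -0.34 but an upper quartile of only -0.18. Less RNA from dendritic cells stays open by fold changes too, since their 7 measured markers had a median of -0.51 and a lower quartile of -0.75. However, 4 of them, with Itgax at 0.127 to 0.87 CPM, lay under 1 CPM in KO cohort WT, and the sort for B220, PNA and CD95 would remove such cells. The amounts of RNA were not weighed. H2-Aa lay at 1500 to 1650 CPM in KO cohort WT and at 979 to 1140 CPM in KO, and the marker Flt3 at 45.3 to 56.5 and 34.2 to 38.5 CPM. A change caused by the lost acetyltransferase may account for the fall of class II genes too and could not be separated from these explanations. For KO against wild type, the real split called 216 genes and the other splits 0 at most, and 10 splits are too few for a share under 0.05, as they are for the lists, where 8 of the 10 called as many, with 6 for the real split and 9 at most for another.

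The rise of MHC class I and interferon gamma genes in RH HOMO was weighed in the same way over the 38 measured genes of both lists, with a median of 0.39. Leaving out RH cohort WT 1 gave 0.35 and a term for sex gave 0.37, so neither the first library nor the excess of female animals accounts for it alone. RH HOMO 2 was not left out for this median. It had the highest value of Irf1, at 109 CPM against 76 and 84.6 CPM in RH HOMO 1 and 3. RNA from follicular naive B cells may contribute, since their markers had a median of 0.20 and an upper quartile of 0.38, which overlaps the lower quartile of 0.23 of both lists, and the sort for CD95 and PNA would remove such cells. RNA from macrophages and monocytes stays open by fold changes as well, since their 18 measured markers had a median of 0.68, although 12 of them lay under 1 CPM in RH cohort WT and Apoe was at -0.55 ± 0.16 (SE, adjusted p = 0.0968). The amounts of RNA were not weighed. Irf1 lay at 38 to 45.7 CPM in RH cohort WT and at 76 to 109 CPM in RH HOMO. Adgre1, the marker with the smallest p, lay at 0.734 to 1.56 and at 2.56 to 2.9 CPM. For Tapbpl alone, a linked segment of distal chromosome 6 stays open too. The RH allele stays among the open explanations. Of 10 splits, too few for a share under 0.05, 2 called as many genes, with 261 for the real split and 707 for the other, and 7 as many lists, with 9 and 13 at most.

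The 840 genes that differed between the wild type groups were the third pattern. If RH cohort WT 1 alone were the source, the fold changes without it would shrink to near 0, but their slope on the full ones was 0.877, although only 70 genes were then called. If that library had belonged to the knockout cohort, as its batch tag says, it would lie near the KO cohort WT libraries in those 70 genes, but its median position was 0.856 on a scale from 0 for KO cohort WT to 1 for the other RH wild types. A term for the mitochondrial share left 0 calls by edgeR, with 1706 genes at an unadjusted p under 0.05, but fold changes kept a slope of 0.83 while the median standard error of the called genes rose from 0.138 to 0.173. The animals, the dates and the preparation of the cohorts may each differ and cannot be told apart, and the 10 splits, with 840 for the real one and 0 at most for another, are too few for a share under 0.05.

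For RH HET against wild type, 2 of 35 splits called as many genes, with 3 for the real split and 54 for the highest other, and 6 of 35 called as many lists, with 14 and 18. For RH HOMO against RH HET, all 35 splits reached the real count of 0 genes, with 1060 at most, and 16 of 35 reached the 8 lists, with 12 at most. The splits with the most genes set libraries apart by mitochondrial share, and as fully by the TMM factor and the share of counts in the highest genes. These measures were not told apart. The 54 genes came with RH cohort WT 1, RH cohort WT 2 and RH HET 2 on 1 side, at 5.84% or more against 4.72% or less. The 707 genes came with RH cohort WT 1, RH cohort WT 2 and RH HOMO 2, at 5.28% or more against 4.72% or less. The 1060 genes came with RH HET 2, RH HOMO 1 and RH HOMO 2, at 4.59% or more against 4.32% or less. Their TMM factors were 0.9655 to 0.9933 against 1.002 to 1.016. This points to a structure of the RH libraries that the genotype does not explain.

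Shared calls were set against 100 drawn splits each. For KO and RH HOMO, drawn from the 200 splits within cohorts, 1 of 100 shared as many, the real one, with 40 genes against 6 at most, and 3 at most in the first 40. That count says little, because 90 of the 100 broke up the KO group, and 89 of those 90 shared 0, with 4 at most. Of the 10 that kept the KO group together, 1 shared as many, with 40 for the real split and 6 at most for another, and such splits are too few for a share under 0.05. For RH HET and RH HOMO, drawn from 4200, 4 of 100 shared as many, with 3 genes for the real split and 683 for the highest other, and 1 of the first 40 did. That share is below 0.05, but the split with 683 compared groups against RH cohort WT 1, RH HET 2 and RH HOMO 2, which again points to a structure of the RH libraries.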

How the results depend on the processing

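The terms for sex and for the mitochondrial share, leaving out RH cohort WT 1 and RH HOMO 2 together, and leaving out mitochondrial and rRNA-like genes were chosen after seeing the data, and the other alternatives before. Numbers of genes are given as higher and lower. Except where a clause gives it, the cause was not tested. No paired analysis was possible because the labels carry no replicate numbers and those used here were given in accession order. Some called genes lay near 1 CPM, such as Thy1, at 0.2 to 1.87 CPM in RH cohort WT and RH HOMO. How well differences were resolved at such low levels was not tested. Of named genes under these alternatives, 980 values stayed on the same side of the threshold, 144 no longer passed, 1 newly passed (Crebbp in RH HET with limma-voom, at 0.449) and 15 turned sign, and of lists 190 stayed, 28 no longer passed and 9 turned. With 1 library left out, the numbers were 322, 182 and 13 for genes and 285, 63 and 4 for lists.

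DESeq2 size factors, and likewise leaving out immunoglobulin and T cell receptor genes, gave 0 lower genes in RH HET. Without a count filter RH HET had 4 and 15, RH HOMO 158 higher, RH HOMO against RH HET 11 and 52, the difference of effects 51 and 58, and the wild types 659 lower. DESeq2 called 271 and 286 in KO, 17 and 34 in RH HET, 257 and 409 in RH HOMO, 36 and 96 in RH HOMO against RH HET, 109 and 134 for the difference of effects and 1182 and 906 in the wild types, with overlaps of 114 for KO and RH HOMO and 40 for RH HET and RH HOMO. The quality-weighted limma-voom fit called 477 and 467, 127 and 117, 535 and 585, 44 and 45, 315 and 330, and 2232 and 2125 in the same order.

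By construction, an adjusted p under 0.1 gave more, 184 and 192 in KO, 197 and 290 in RH HOMO, 43 and 59 for the difference of effects and 1255 and 919 in the wild types. A log2 fold of at least 1 gave fewer, 43 and 44 in KO, 1 and 0 in RH HET, 35 and 86 in RH HOMO, and 64 and 71 in the wild types. Only the libraries compared gave 331 and 368 in KO, 0 and 0 in RH HET, 0 and 0 in RH HOMO, 1 and 1 in RH HOMO against RH HET, 3 and 7 for the difference of effects and 929 and 925 in the wild types. With the conflicting library in the KO cohort, RH HET had 0 higher, RH HOMO 19 and 83, the difference of effects 4 and 11, and the wild types 1 and 0. All 6 wild type libraries as 1 control group gave 185 lower in KO, 6 and 5 in RH HET, and 320 and 337 in RH HOMO.

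With an estimated correlation 0 lists were called in any comparison, higher or lower. Fry called 2 lower lists in KO, 0 in RH HET, 2 higher and 1 lower in RH HOMO, 0 in RH HOMO against RH HET, and 3 higher and 1 lower for the difference of effects. A term for sex gave 1 higher list in KO, 2 lower genes in RH HET, and 2 and 5 genes in RH HOMO against RH HET, and the MHC class II list in KO stayed at a median of -0.434. Without RH cohort WT 1 and RH HOMO 2, KO had 224 and 237, RH HET 4 and 2, RH HOMO 49 higher, RH HOMO against RH HET 2 lower with 3 higher and 1 lower lists, the wild types 508 lower, and RH HET and RH HOMO shared 5. A term for the mitochondrial share gave 186 lower in KO, 0 and 0 in RH HET with 1 higher and 3 lower lists, 249 lower in RH HOMO, 0 and 0 in the wild types, and 0 shared by RH HET and RH HOMO.

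Leaving out each library in turn gave 18 to 40 higher and 18 to 47 lower genes in KO, with 0 to 2 higher and 3 to 8 lower lists. RH HET had 0 to 4 and 0 to 1, with 1 to 7 and 4 to 9 lists. RH HOMO had 34 to 101 and 81 to 157, with 2 to 8 and 3 to 7 lists. RH HOMO against RH HET had 0 to 1 lower genes, with 3 to 7 and 1 to 4 lists. The difference of effects had 1 to 22 and 5 to 45, with 3 to 6 lower lists, and the wild types had 1 to 1119 and 2 to 749. The overlaps ran from 8 to 62 for KO and RH HOMO and from 0 to 7 for RH HET and RH HOMO. A group left with fewer libraries drew its spread from the others.

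Signs turned in Crebbp and Ep300, which were called in no comparison by edgeR, and in lists. Crebbp in RH HOMO, at 0.014, was at -0.002 with a minimum of 1 CPM, -0.059 with the conflicting library in the KO cohort, -0.204 against all 6 wild types, -0.082 with sex, -0.247 with the mitochondrial share and -0.16 to 0.237 with 1 library left out. Crebbp in KO was at 0.044 against all 6 wild types. For the difference of effects Crebbp was at -0.041 with the conflicting library in the KO cohort, -0.025 with sex, -0.069 with the mitochondrial share and -0.023 to 0.374 with 1 library left out. Ep300 in RH HOMO was at 0.263 with limma-voom, 0.224 without RH cohort WT 1 and RH HOMO 2, and -0.31 to 0.267 with 1 library left out, and for the difference of effects Ep300 was at 0.244, 0.202 and -0.334 to 0.242. Ep300 was at -0.036 in KO and -0.088 in RH HET with the mitochondrial share, and at -0.081 to 0.126 in KO with 1 library left out.

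In RH HET the mitochondrial share turned the list medians of nuclear-encoded oxidative phosphorylation to 0.113, apoptosis regulators to -0.032, MYC targets to 0.008, cytosolic ribosomal proteins to 0.111 and naive B cell markers to -0.019, and in RH HOMO that of DNA replication to 0.053. Oxidative phosphorylation in RH HET was also at 0.013 without RH cohort WT 1 and RH HOMO 2, and at -0.169 to 0.013 with 1 library left out. In RH HOMO against RH HET, chromatin regulators were at 0.003 and ribosomal proteins at -0.061 without both libraries, and at -0.247 to 0.002 and -0.061 to 0.37 with 1 left out. Ribosomal proteins for the difference of effects were at -0.037 to 0.421 with 1 library left out.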

Other observations

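The tests on KO calls in RH HOMO and on windows of chromosomes were chosen after the result was seen, and the one that allows for gene density after the first had given its p. Those on KO calls in RH HET and on genes near Crebbp were chosen before.

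Some lists that the comparisons above did not describe were looked at in KO and RH HOMO. Cholesterol synthesis genes had medians of 0.07 in KO and -0.09 in RH HOMO, mitosis genes -0.01 and -0.07, and MYC targets -0.05 and -0.05, with 0 members called in either by edgeR. Memory B cell genes had a median of 0.45 in KO, with Bcl2, an inhibitor of apoptosis, at 0.87 ± 0.26 (SE, adjusted p = 0.118), and 0 of 19 members called, where 2 were higher when adjusted over the list alone. In RH HOMO the median was 0.17, with Gpr183 called higher and Tle3 lower, and 4 were higher and 3 lower when adjusted over the list alone. Marginal zone and B1 cell markers had a median of -0.36 in KO and -0.20 in RH HOMO, with Cd5 at -1.96 ± 0.62 (adjusted p = 0.151) in KO.

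Genes called in KO were followed into the RH libraries, whose controls are different. In RH HOMO, 156 of the 216 genes (72.2%) had the sign of the KO change, with a median signed difference of 0.26, and 4 of 10 splits reached as many, with 157 at most in another split. In RH HET, 146 (67.6%) did, with a median of 0.09, and 3 of 35 splits reached as many, with 160 at most. The hypothesis that RH HET carries a weaker form of the KO change therefore gained nothing from the number of signs.

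The 3 genes called in RH HET lie on distal chromosome 6, and 12 of the 259 genes called in RH HOMO that have a position lie in 1 window of 20 Mb there. They include Plbd1, Dusp16, Emp1 (-2.27), Etv6 (0.70), Tapbpl and Apobec1 (0.56), of which Emp1 and Etv6 were picked after their values were seen. So was Gm44223, a predicted gene model outside the naming rule, at 7.43 in RH HOMO, 7.15 in RH HET, where it was not called, and 0 in KO. A segment of another strain linked to this region was the hypothesis. In 10000 random draws of as many tested genes the highest count in any window had a median of 10, and the permutation p was 0.14. That count favours windows dense in genes, and a test by the number of tested genes in each window expected 2.86 calls where 12 lay, with a permutation p of 0.0176. For RH HET it expected 0.027 calls where 3 lay (permutation p = 0.0001), but RH HET and RH HOMO share their controls. A linked segment therefore stays open for these genes, and genotypes along the chromosome are not given in the sources used here. For KO the window with the most calls lay on chromosome 17 with 14 calls and a permutation p of 0.0049, but without the MHC lists the highest window held 9 calls and p was 0.45. By gene density the permutation p was 0.0069, for a window on chromosome 17. Without those lists the window with the least p lay on chromosome 1, with a permutation p of 0.083. That value does not describe chromosome 17, so a linked segment and the joint fall of MHC genes cannot be told apart. Of 39 genes called in KO and RH HOMO in the same direction that have a position, 1 lay within 20 Mb of Crebbp, where 0.557 would by chance (Fisher's exact test, one-sided, p = 0.43).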
